A study of Rattus norvegicus with 6 samples.

How the data were processed

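The series holds 6 arrays of cultured vascular smooth muscle cells from the aorta of Wistar rats aged 8 weeks, 1 array for each of 6 treatments. Per the labels, confluent cells grown in 10% serum on plates coated with laminin at 20 µg/ml were kept without serum for 48 h, or for 24 h followed by 24 h with 100 µM hydrogen peroxide (H2O2), and RNA from 3 independent experiments was pooled for each array. Adenoviral vectors were added at the start of starvation. They carried nuclear EGFP (nEGFP, a marker protein, 100 moi), dominant negative JNK1 (JNK1-APF, 100 moi), or constitutively active MKK7 (MKK7ED, 33 moi, a kinase that activates JNK) together with normal JNK1 (JNK1-WT, 66 moi). Moi is the number of virus particles able to infect added per cell.

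The deposited values are 1 signal intensity per probe set and array on a linear scale, made by the authors from Affymetrix GeneChips hybridised with biotinylated cRNA, per the labels. The software that summarised probes into signals and its version are not given in the sources used here, nor are detection calls. The values had been scaled before deposit: the mean of each array without the lowest and highest 2% of probe sets was 150 with a spread of 0.252% over the 6 arrays, within the 5% allowed for using them unchanged, so no further normalization was applied. Array medians ran from 31.8 to 36.6, and 57.9% to 61.3% of probe sets lay above the floor defined next. Signal ratios of 3' to 5' control probe sets were 1.06 to 1.25 for actin and 1.08 to 1.38 for GAPDH. Correlations of log2 signals between arrays, across genes, were 0.961 to 0.981.

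Values under the 40th percentile of all signals, 20.4, were set to it, and a fold with 1 array at or under this floor is a lower bound, written as at least N-fold. Of 8799 probe sets, 59 were array controls. The platform annotation listed 7326 probe sets, of which 7006 that were not controls carried 1 gene symbol, 308 carried several and were not named, and 1473 probe sets were not listed. Of 7018 probe sets with 1 symbol, 6994 were matched by Entrez gene number to the current rat gene table, and 0 symbols needed updating. Where a gene had several probe sets, as 1565 of 4736 genes did, the one with the highest mean signal was used. The 3657 genes above the floor on at least 1 array were measured.

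No group has replicates, so the calls are by size. Tests were possible only with limma fits that assume additive effects, and were run as alternatives. A gene was called by size alone, at least 2-fold with the higher array above the floor. Of each pair of comparisons that share no array, the overlap of calls was set beside the number that independent lists would share. The robust spread of the difference between the H2O2 effects without and with nEGFP virus, divided by the square root of 2, served as the error of a comparison of 2 arrays. It holds any true difference between the infection states, which raises it. Values set to the floor lower it, and a robust spread gives little weight to extreme genes, so it is not an upper bound. No array with a JNK vector entered it. It came to 0.44 on the log2 scale for the 1998 genes with a mean signal up to 100, 0.40 for the 1083 genes from 100 to 400, and 0.30 for the 576 genes above 400. The number of arrays limits the precision of every value.

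Each of 22 gene lists was described by the median log2 fold of its measured members and the percentile of that median among 10000 random lists of the same size matched on mean signal, which describes these arrays only. The lists were matrix structural genes, collagen processing and crosslinking enzymes, matrix proteases, protease inhibitors, smooth muscle contractile genes, inflammatory mediators, antioxidant and NRF2 target genes, p53 and growth arrest genes, proliferation genes, immediate early and AP-1 genes, unfolded protein and heat shock genes, sterol and fatty acid synthesis genes, interferon response and antigen presentation genes, JNK pathway components, osteochondrogenic genes, hypoxia and glycolysis genes, growth factors and their binding proteins, ribosomal proteins, and markers of endothelial cells, macrophages and leukocytes, fibroblasts and adventitia, and adipocytes and Schwann cells. The study is known to have named members of the lists of collagen enzymes, matrix proteases and inflammatory mediators from these samples, so these 3 lists are not independent evidence of a direction.

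Genes named in the text followed a rule. These were the targeted kinases, then up to 10 genes each way with the largest smaller fold among those at least 2-fold in both H2O2 comparisons, up to 12 each way among those opposite in the JNK comparisons, up to 8 each way among those shared by both virus comparisons, the 8 largest each way in each JNK comparison, and up to 4 members of each list with the largest fold. The rule, the lists, the floor, the choice of probe set and the alternative settings were fixed before the data were examined. The alternative settings were quantile normalization, equal array medians, floors at the 20th and 60th percentile, no floor (values under 1 set to 1), the mean of all probe sets of a gene, a 3-fold threshold, and for the H2O2 and virus effects limma on 4 arrays with both factors and 1 residual degree of freedom, at an adjusted p of 0.05. A limma fit on all 6 arrays with H2O2, virus, JNK1-APF and MKK7ED as additive factors, also with 1 residual degree of freedom, was added after the data were seen.

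The calculations were tested on 6 simulated arrays in which each of 3657 genes had its mean log2 signal over the real arrays plus random error of the measured size. Of 100 genes changed 2-fold in the simulated MKK7ED comparison, 52 were called, and 19 were called in opposite directions in both JNK comparisons. Of 100 genes changed 4-fold, 100 were called in one and 68 in both, while of 3457 unchanged genes 53 were called in one and 1 in both. In simulated data for limma's H2O2 effect, 68 of 100 genes changed 2-fold and 100 of 100 changed 4-fold were recovered, and 9 unchanged genes were called. In simulated data for the JNK1-APF comparison in the limma fit on 6 arrays, 27 of 100 genes changed 2-fold and 97 of 100 changed 4-fold were recovered. In that fit 4 unchanged genes were called. Both limma simulations drew errors of a single size per range of mean signal and held additive effects only. Real genes may vary less evenly, so these numbers do not give the power of limma on the real arrays. The simulated size calls also drew normal errors of a single size per range. Extreme values may be more frequent on real arrays, so the 53 and 1 unchanged genes called do not give the number of false calls there. Of 100 unchanged lists of 30 genes, 3 fell outside the middle 95% of random lists, and 100 of 100 lists shifted by 0.5 did. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.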

Results

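The 6 arrays allow 6 comparisons: H2O2 against no H2O2 in uninfected cells and in cells with the nEGFP virus, JNK1-APF against nEGFP with H2O2 present, MKK7ED plus JNK1-WT against nEGFP without H2O2, and nEGFP virus against no virus without and with H2O2. Each treatment has 1 array of RNA pooled from 3 experiments, so there are no replicates and every size below describes these arrays. Limma, fitted to the 4 arrays without JNK vectors with 1 residual degree of freedom, called 0 genes for H2O2 and 0 for virus at an adjusted p of 0.05, with 167 and 296 at an unadjusted p of 0.05. Limma on all 6 arrays called 0 genes for JNK1-APF and 0 for MKK7ED, with 190 and 222 at an unadjusted p of 0.05 against 182.85 by chance and smallest adjusted p of 0.712 and 0.658. Of the kinases brought in by the vectors, Mapk8 (JNK1) was under the floor on all 6 arrays, with signals of 4.1 to 8.2, and Map2k7 (MKK7) has no probe set of its own here, so the arrays do not show how strongly the vectors were expressed.

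In uninfected cells H2O2 left 78 genes at least 2-fold higher and 82 lower, or 60 and 96 with equal array medians, 285 and 213 with the floor at the 20th percentile and 495 and 296 without a floor. Matrix structural genes were lower as a group: 24 of 27 lay below the untreated array, with a median log2 fold of -0.29 at percentile 0 of the random lists. Dcn (decorin, a proteoglycan that binds collagen) was 3.13-fold lower, Fmod (fibromodulin, of the same family) 2.65-fold and Nid1 (nidogen, of the basement membrane) 2.13-fold lower, while Tnc (tenascin C) was 1.98-fold higher. Sterol and fatty acid synthesis genes were lower in 17 of 20 cases, at a median of -0.44 (percentile 0), with Acat2 2.18-fold, Idi1 1.85-fold, Cyp51 1.78-fold and Fdps 1.78-fold lower. Antioxidant and NRF2 target genes went the other way, with 18 of 30 above the untreated array and a median of 0.21 (percentile 100.0), which was 0.13 with equal array medians and 0.0255 with a floor at the 60th percentile. Nqo1 (a quinone reductase) was 2.81-fold, Ephx1 (an epoxide hydrolase) 2.66-fold and Gsta1 (a glutathione transferase) 2.16-fold higher, though Gclm (of glutathione synthesis) was 2.13-fold lower.

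Several smaller group shifts went with these in uninfected cells. Inflammatory mediators had a median of -0.22 (percentile 0.3), which was 0.00 with a floor at the 60th percentile and -0.36 with a lower floor or none. Of these, Lbp was 2.39-fold, Vcam1 (a leukocyte adhesion receptor) 2.29-fold and Icam1 1.89-fold lower and Nos2 (inducible nitric oxide synthase) 1.97-fold higher. Unfolded protein and heat shock genes stood at -0.16 (percentile 0.3), with Trib3 3.27-fold lower. Hypoxia and glycolysis genes were at -0.19 (percentile 0.55), with Pfkp 1.54-fold lower, and immediate early and AP-1 genes at -0.13 (percentile 1.01), with Klf4 3.72-fold and Egr2 2.35-fold lower. With the floor at the 60th percentile the hypoxia median was -0.0655 and the immediate early median -0.05. Equal array medians gave -0.21 for immediate early and -0.24 for unfolded protein genes, and the mean of all probe sets gave -0.0868 for the latter. Collagen processing and crosslinking enzymes had a median of -0.18 (percentile 2.42), with P4ha1 (a collagen prolyl hydroxylase) 1.62-fold and Plod3 (a lysyl hydroxylase) 1.39-fold lower. Among single members of lists without a shift, Igfbp5 was at least 7.95-fold, Agtr1a (an angiotensin II receptor) 3.82-fold, Plat (tissue plasminogen activator) 2.5-fold and Ddit3 2.66-fold lower, and the p53 target Ccng1 was 2.01-fold higher. Ribosomal proteins had a median of 0.06 (percentile 98.6), which turned to -0.025 with equal array medians.

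In cells with the nEGFP virus H2O2 left 159 genes higher and 135 lower, or 124 and 176 with equal array medians and 57 and 67 with the floor at the 60th percentile, and the contractile program was low. Of 20 smooth muscle contractile genes 18 were below the array without H2O2, at a median of -0.80 (percentile 0): Pln (phospholamban) was 3.84-fold, Cald1 (caldesmon) 3.20-fold, Acta1 3.12-fold and Actg2 (smooth muscle gamma actin) 2.99-fold lower. Sterol and fatty acid synthesis genes were higher in 19 of 20 cases, at a median of 0.84 (percentile 100.0), with Scd (a fatty acid desaturase) 3.85-fold, Fdps 3.12-fold, Lss 2.53-fold and Cyp51 2.51-fold higher. Against the untreated array the sterol median was -0.49 with nEGFP alone and only 0.24 with nEGFP and H2O2, so a low nEGFP array makes up part of this shift. The p53 and growth arrest genes had a median of 0.78 (percentile 99.99), with Gdf15 3.91-fold, Cdkn1a (p21, a cell cycle inhibitor) 2.39-fold and Ddit3 2.28-fold higher and Btg1 2.20-fold lower. Proliferation genes were also higher, at 0.30 (percentile 98.1), a value that was 0.19 with equal array medians and 0.00 with a floor at the 60th percentile, with Top2a (a topoisomerase of dividing cells) 4.66-fold, Prim1 2.34-fold, Tyms 2.29-fold and Ccnb1 2.19-fold higher.

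In the same comparison growth factors and their binding proteins had a median of -0.25 (percentile 0.16), again 0.00 with the floor at the 60th percentile, with Tgfb3 5.10-fold, Edn1 (endothelin 1) 3.11-fold and Bdnf 2.85-fold lower and Fgf2 at least 2.97-fold higher. Protease inhibitors stood at -0.45 (percentile 1.19), or -0.0499 with that floor, with Serping1 2.18-fold, Tfpi 1.75-fold and Timp3 1.60-fold lower and Timp1 1.68-fold higher. Matrix structural genes, at -0.15 (percentile 10.8), and collagen enzymes, at -0.33 (percentile 3.82), lay within the middle 95% of random lists. Among them Nid1 was at least 4.82-fold, Fmod 4.08-fold, Col15a1 2.52-fold, Lox (lysyl oxidase) 2.07-fold and Plod1 2.06-fold lower. The antioxidant median was 0.17 (percentile 96.5), with Taldo1 2.48-fold and Hmox1 (heme oxygenase 1) 2.36-fold higher. Nos2 was at least 6.05-fold, Cxcl10 (a chemokine induced by interferon) 4.19-fold and Ccl2 (a monocyte chemokine) 2.84-fold higher, within a list of inflammatory mediators whose median was 0.26.

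The 2 H2O2 comparisons share no array, and 9 genes were at least 2-fold higher in both against 3.39 for independent lists, 11 lower in both against 3.03, and 3 and 4 went in opposite directions against 2.88 and 3.57. With the floor at the 20th percentile 47 were higher and 20 lower in both, and without a floor 87 and 39. The overlap of 20 genes was 10 with the mean of all probe sets, 7 and 67 with the floor at the 60th and 20th percentile, 126 without a floor and 1 at 3-fold. For H2O2, the 167 genes of limma compare with 182.85 by chance, with a smallest adjusted p of 0.757. Higher in both, as folds without and with virus, were Sds (serine dehydratase) 3.19 and 3.16, Gja4 (connexin 37) 2.67 and 2.66, Atp1b2 (a sodium pump subunit) 2.38 and 2.49, Nqo1 2.81 and 2.18, Ptger3 (a prostaglandin E2 receptor) 2.54 and 2.18. With 1 array at the floor in at least 1 of the comparisons, Cds1 was 2.33-fold and at least 4.58-fold, Kng2 2.69-fold and at least 2.94-fold, Dll3 at least 3.93-fold and 2.26-fold, and Ctrc at least 2.13-fold and at least 5.01-fold higher. Lower in both were Fmod 2.65-fold and 4.08-fold, Dcn 3.13-fold and 2.20-fold, Vcam1 2.29-fold and 2.34-fold, Nid1 2.13-fold and at least 4.82-fold. Further genes lower in both included St3gal5 (2.25 and 3.02), Serping1 (2.93 and 2.18) and Psat1 (2.36 and 2.06), with Prickle2 at least 5.72-fold and 2.17-fold, Smim5 at least 2.49-fold and at least 3.20-fold, and Pcmtd2 2.02-fold and at least 2.13-fold lower. Across all measured genes, which are not independent replicates, the 2 sets of log2 folds had a correlation of 0.11.

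**Figure D1:**
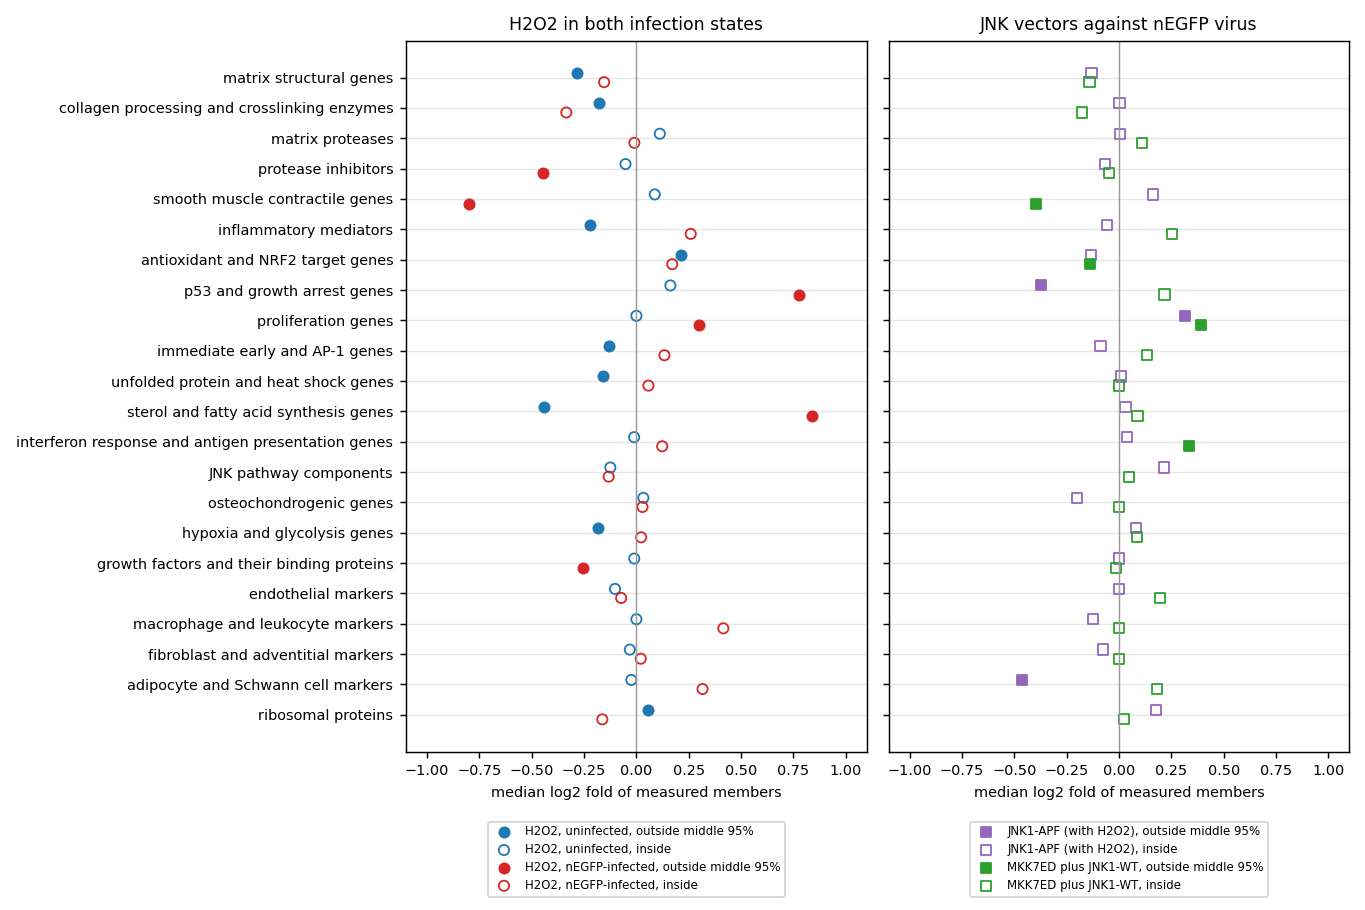
Median log2 fold of each gene list (horizontal axis) in the comparisons for H2O2 and for JNK vectors. The virus comparisons are not drawn. Sterol and fatty acid synthesis genes lay at -0.44 with H2O2 in uninfected cells and at 0.84 in infected cells, and smooth muscle contractile genes at 0.09 and -0.80.

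With H2O2 present, JNK1-APF left 77 genes higher and 179 lower than nEGFP, or 99 and 133 after quantile normalization and 133 and 114 with equal array medians. Proliferation genes were higher as a group, at a median of 0.32 (percentile 99.9), or 0.0841 with a floor at the 60th percentile, with Hmgb2 2.68-fold, Cdk2 2.51-fold and Mcm5 2.25-fold higher, although Ccnb1 was 2.06-fold lower, and the replication factor gene Rfc4 was 3.55-fold higher. The p53 and growth arrest genes had a median of -0.37 (percentile 2.22), with 5 of 9 lower and 4 higher, and the median was -0.17 with equal array medians and -0.24 with the mean of all probe sets. Among them were Gdf15 3.08-fold, Bcl2l1 1.77-fold and Cdkn1a 1.76-fold lower. Against the untreated array the p53 median was 0.99 with nEGFP and H2O2. It was 0.17 with JNK1-APF, 0.21 with nEGFP, 0.16 with H2O2 alone and -0.02 with MKK7ED. The p53 medians of 0.78 with H2O2 in infected cells and 0.71 with virus and H2O2 use that same high array. These results are not independent, and a deviation of that array cannot be told apart from an effect of JNK1-APF. Rsad2 (viperin, induced by interferon) was 12.2-fold and Cxcl10 4.10-fold higher, while the interferon list as a whole stood at 0.04. Nos2 was at least 6.05-fold, Il1a (interleukin 1 alpha) at least 3.02-fold and Cxcl6 2.19-fold lower, with the inflammatory list at -0.06. Cald1 was 2.18-fold and Csrp2 2.02-fold higher among contractile genes, whose median was 0.16, and matrix structural genes and collagen enzymes were at -0.13 and 0.00.

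Other genes with large sizes under JNK1-APF were Stk39, at least 6.11-fold higher on 1 of its 3 probe sets, Syt5 5.33-fold, Iqsec1 4.82-fold, Nrarp 4.0-fold and Ivns1abp 3.76-fold higher. Lims1 was 8.46-fold lower and Mrpl45 at least 6.92-fold lower. Of the 8 largest lower values, 6 belong to probe sets listed at 0 on the JNK1-APF array and have no fold: Pdha1 (signal 932 with nEGFP and H2O2), Asnsd1 (349), Scamp2 (240.7), Ppdpf (221.5), Rasl11b (161.6) and Timm29 (132). These probe sets lie in 1 stretch of the deposited table, as do those of Lims1, Iqsec1, Nrarp and Ivns1abp, and other probe sets of Pdha1, Asnsd1 and Rasl11b had log2 folds of -0.08, 0.06 and 0.13. Markers of adipocytes and Schwann cells stood at -0.46 (percentile 0.95), with Ngfr 2.85-fold and Mag 2.27-fold lower and Adrb3 at least 2.46-fold lower, and ribosomal proteins were at 0.18 (percentile 97.4). The marker median was 0.00 with the floor at the 60th percentile, -0.26 with equal array medians and -0.27 with the mean of all probe sets. Within lists that did not shift, Zfp36 2.84-fold, Fosl2 2.35-fold and Msx2 2.64-fold were lower and Dusp6 was 2.28-fold higher.

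**Figure D2:**
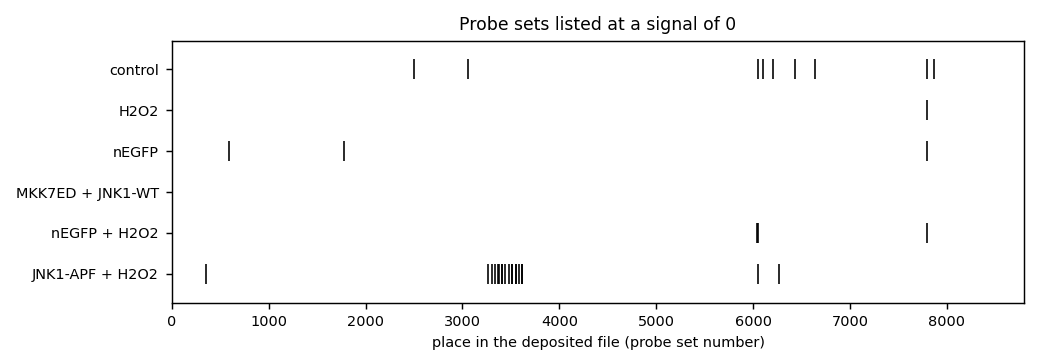
Probe sets listed at 0 by array (vertical axis) and place in the deposited table (horizontal axis). On the JNK1-APF array 16 of 19 lie between places 3267 and 3617 of 8799.

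MKK7ED plus JNK1-WT left 171 genes higher and 84 lower than nEGFP without H2O2, or 131 and 114 with equal array medians. Proliferation genes were higher, at a median of 0.39 (percentile 99.9), or 0.17 with a floor at the 60th percentile, with Top2a 4.30-fold, Lmnb1 at least 2.96-fold, Mcm5 at least 2.42-fold and Ccne1 2.26-fold higher. The proliferation list was higher with JNK1-APF too, at 0.32, although the vectors act on JNK in opposite ways. Against the untreated array its median was 0.43 with MKK7ED, 0.96 with JNK1-APF and 0.46 with nEGFP and H2O2. Contractile genes were lower, at -0.40 (percentile 0.02), or -0.19 with the mean of all probe sets, with Pln 3.37-fold and Cald1 1.99-fold lower. Against the untreated array the contractile median was 0.01 on the MKK7ED array and 0.28 on the nEGFP array. Contractile genes were thus low against nEGFP but not against untreated cells. Interferon response and antigen presentation genes stood at 0.34 (percentile 98.6), or 0.0311 with the 60th percentile floor, with Rsad2 at least 3.51-fold, Psmb8 2.04-fold and Irf7 1.71-fold higher and Irf3 2.37-fold lower. Antioxidant genes were at -0.14 (percentile 1.9), which was -0.25 with equal array medians and -0.038 with the 60th percentile floor. Their medians against the untreated array were 0.07 on the MKK7ED array and 0.21 on the nEGFP array. Gsr (glutathione reductase) was 4.29-fold lower on 1 of its 3 probe sets, Sod2 2.5-fold, Cat (catalase) 2.49-fold and Nqo1 2.15-fold lower.

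Jun (2.12-fold) and Ier3 (2.03-fold) were higher with MKK7ED, as was Jund, at least 2.73-fold, in an immediate early list with a median of 0.13. In the inflammatory list, at 0.25, Nos2 was at least 9.58-fold, Cxcl10 4.99-fold and Csf3 2.22-fold higher and Vcam1 2.28-fold lower. Matrix structural genes (-0.14) held Nid1, at least 4.82-fold lower, Col11a1 2.85-fold and Fmod 2.37-fold lower, and Timp3 (an inhibitor of matrix metalloproteinases) was 2.74-fold lower. The size rule also named Ces1dl1 5.73-fold, Ckmt1 (a mitochondrial creatine kinase) 5.63-fold, Fggy 4.70-fold, Hsf1 4.68-fold and Grk4 4.35-fold higher, and Cyb5a 7.29-fold, Pfkl (liver type phosphofructokinase) 5.06-fold and Sec22a 4.79-fold lower. Against the untreated array Ces1dl1 was lower with MKK7ED, at a log2 fold of -0.63. Lower than nEGFP, with the MKK7ED array at the floor, were Ahr (at least 3.95-fold), Svop (at least 3.74-fold) and Gja4 (at least 3.67-fold). Kcna6 (a potassium channel) had a signal of 1887.4 on the MKK7ED array and 3.3 to 18.2 on the other 5, at least 92.5-fold higher, on 1 of its 2 probe sets.

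The 2 JNK comparisons also share no array, and 33 genes were higher with MKK7ED plus JNK1-WT and lower with JNK1-APF, against 8.37 for independent lists, while 5 were the other way round against 1.77. In the same direction with both vectors, 8 were higher against 3.60 and 3 lower against 4.11. With equal array medians the counts were 20 and 14, and after quantile normalization 26 and 11. The sum of 38 was 16 with the mean of all probe sets, 10 and 119 with the floor at the 60th and 20th percentile, 197 without a floor and 1 at 3-fold. Higher with MKK7ED and lower with JNK1-APF were, among others, Nos2, at least 9.58-fold and at least 6.05-fold, Gdf15 2.43-fold and 3.08-fold, and Hyou1 (a chaperone of the endoplasmic reticulum) 2.55-fold and 2.5-fold. Flot1 (2.75 and 2.79), Cyp2e1 (2.5 and 2.71), Fam83f (2.39 and 2.98) and the chloride channel Cftr (2.32 and 2.40) had similar folds in both. With bounds, Cds1 was at least 3.67-fold and 2.8-fold, Ctrc at least 3.80-fold and 2.52-fold, Adrb3 (the beta 3 adrenergic receptor) 3.47-fold and at least 2.46-fold, Slc6a2 (the noradrenaline transporter) at least 2.52-fold and 2.48-fold, and Nxph4 at least 2.56-fold and at least 2.49-fold. Lower with MKK7ED and higher with JNK1-APF were Gm2a (3.40 and 2.15), Hspa9 (2.32 and 2.45), Acvr1 (a bone morphogenetic protein receptor, 2.10 and 2.51), Vps26a (2.06 and 2.75) and Stk39 (2.57-fold and at least 6.11-fold).

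Some of these values rest on 1 probe set: the 3 other probe sets of Nos2 had log2 folds of 0.22, 0.98 and 0.00 with MKK7ED and 0.00, 0.03 and 0.00 with JNK1-APF, and the second probe set of Flot1 had 0.04 and -0.37. Hspa9 and Stk39 had another probe set of opposite sign in each JNK comparison, and Cds1 had one with MKK7ED, as listed further below. Of the 33 genes, 16 were at least 1.5-fold and 12 at least 2-fold higher on the MKK7ED array than on the untreated array. The log2 fold between these arrays was -0.03 for Flot1, 0.04 for Fam83f, 0.33 for Cyp2e1 and 1.12 for Cftr. Across all measured genes the JNK folds had a correlation of -0.19.

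**Figure D3:**
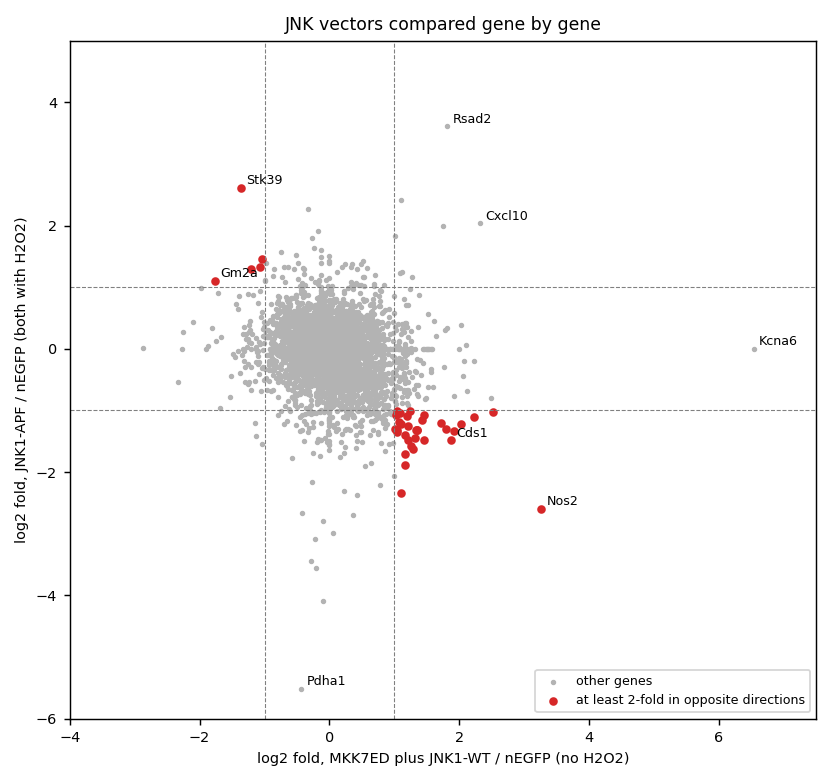
Log2 fold of each gene with MKK7ED plus JNK1-WT (horizontal axis) and with JNK1-APF (vertical axis), each against nEGFP. The 33 genes higher with the first and lower with the second lie at the lower right, among them Nos2 at bounds of 3.26 and -2.60.

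The nEGFP virus alone left 56 genes higher and 106 lower without H2O2, and 183 higher and 154 lower with it. Without H2O2 the counts were 259 and 252 with the floor at the 20th percentile and 408 and 353 without a floor. Among genes higher in both, Psat1 (of serine synthesis) was 5.24-fold and 6.00-fold, Cyb5a 5.66-fold and 5.10-fold, and Nqo1 4.77-fold and 3.71-fold higher. Ripk3 (a kinase of necroptosis) was 2.09-fold and 5.89-fold higher, Scarb2 2.30-fold and 4.21-fold, Ndufa9 2.90-fold and 2.10-fold, Chst10 2.15-fold and 2.17-fold, and Or2b2 at least 2.10-fold and 2.17-fold. Lower in both were, among others, Dcn (4.01 and 2.82), Thy1 (2.69 and 2.37), Syt5 (2.81 and 4.65) and Triobp (2.75 and 2.41), with Grin2a 2.32-fold and at least 3.83-fold, Kcna5 (a potassium channel) at least 2.28-fold and at least 2.78-fold, Nrarp at least 2.25-fold and 2.28-fold, and Serpind1 at least 2.23-fold and 2.23-fold lower. In all, 12 genes were higher in both against 2.8 for independent lists and 12 lower against 4.46, while 4 and 7 went in opposite directions against 2.36 and 5.30, and the correlation across genes was 0.21. The sum of 24 was 15 with the mean of all probe sets, 10 and 100 with the floor at the 60th and 20th percentile, 159 without a floor and 3 at 3-fold. For the virus, the 296 genes of limma compare with 182.85 by chance, with a smallest adjusted p of 0.569.

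Without H2O2, the virus went with lower sterol synthesis genes, 20 of 20 below the uninfected array at a median of -0.49 (percentile 0). Scd was 3.06-fold, Insig1 2.49-fold, Mvk 2.25-fold and Acat2 2.13-fold lower. The median of -0.44 with H2O2 in uninfected cells rests on the same untreated array, so these results are not independent. Against that array the MKK7ED array was at -0.54. Contractile genes were higher, at 0.28 (percentile 99.8), with Actg2 1.71-fold and Acta2 1.60-fold, as were unfolded protein and heat shock genes, at 0.30 (percentile 99.99), with Hspa1a 2.72-fold and Hspa9 2.08-fold higher and Trib3 3.64-fold lower. Antioxidant genes were at 0.21 (percentile 99.9), or 0.12 with the mean of all probe sets, and Sod2 was 2.49-fold higher. Markers of adipocytes and Schwann cells were at -0.38 (percentile 0.685), with Lipe 3.96-fold lower, and at 0.00 with the floor at the 60th percentile or the mean of all probe sets.

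With H2O2 present, the virus went with higher sterol synthesis genes, 16 of 20 at a median of 0.84 (percentile 100.0), with Lss 2.99-fold, Fdps 2.82-fold and Hsd17b7 2.29-fold higher. Contractile genes were lower, at -0.36 (percentile 0.72), with Pln 5.31-fold and Cald1 4.14-fold lower. Proliferation genes stood at 0.50 (percentile 99.99), or 0.15 with the 60th percentile floor and 0.82 with a lower floor or none, with Mcm6 3.82-fold and Prim1 3.71-fold higher. The p53 genes were at 0.71 (percentile 99.9), with Gdf15 3.11-fold higher, and unfolded protein and heat shock genes at 0.50 (percentile 100.0), with Cryab 2.37-fold and Hspd1 2.30-fold higher. Inflammatory mediators were at 0.41 (percentile 99.7), which was 0.0393 with the 60th percentile floor, 0.62 with a lower floor or none and 0.27 with the mean of all probe sets. Of these, Cxcl10 was at least 6.53-fold, Cx3cl1 3.42-fold and Ccl2 2.27-fold higher. Hypoxia and glycolysis genes were at 0.27 (percentile 98.3), with Pkm (pyruvate kinase) 2.0-fold higher but Vegfa 2.79-fold lower, and ribosomal proteins at -0.22 (percentile 2.02).

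**Figure D4:**
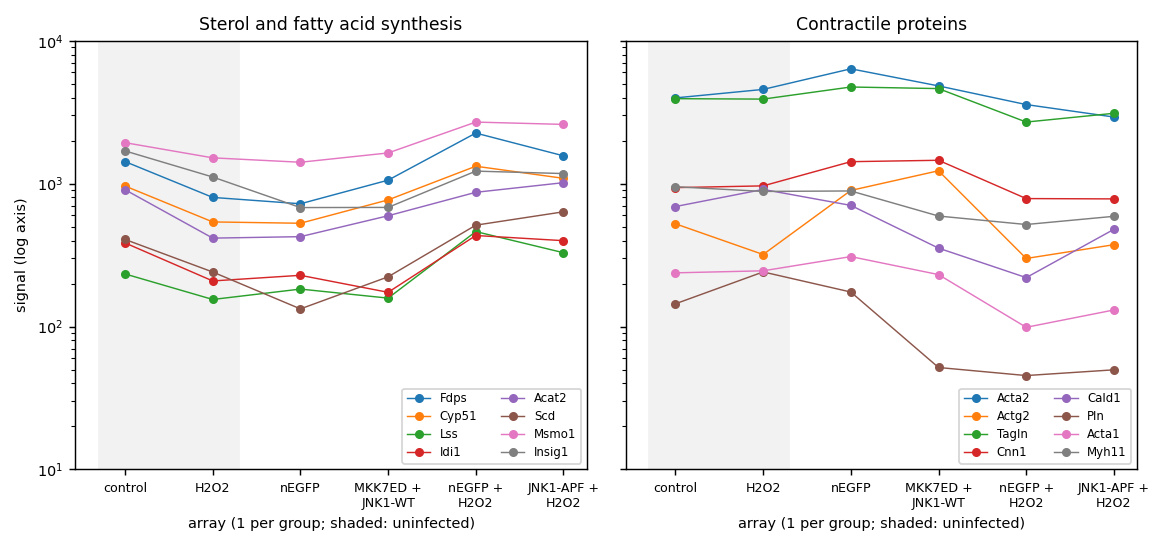
Signal (logarithmic vertical axis) of 8 sterol and fatty acid synthesis genes and 8 contractile genes on the 6 arrays. Fdps was 1.78-fold lower with H2O2 in uninfected cells and 3.12-fold higher in infected cells, where Actg2 was 2.99-fold lower.

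Values from other probe sets of a gene often differed. Among called genes with several probe sets, one of opposite sign was present for 10 of 60, 27 of 136, 27 of 113, 21 of 125, 12 of 73 and 22 of 137, in the order of the comparisons. Of the genes named here for a size of at least 2-fold, those with such a probe set, with its log2 fold, were Bdnf (0.44), Cds1 (-0.06), Nos2 (-0.20), Prim1 (-0.14) and Psat1 (0.81) with H2O2 in infected cells. With JNK1-APF they were Ccnb1 (0.50), Dusp6 (-0.28), Hspa9 (-1.33), Ngfr (0.06), Nos2 (0.03), Stk39 (-0.25 and -0.28) and Zfp36 (0.44). With MKK7ED they were Cds1 (-0.05), Gsr (0.46), Hsf1 (-0.22), Hspa9 (0.83) and Stk39 (0.38), and with virus and H2O2 Dcn (0.16) and Prim1 (-0.01). Others had the same sign but were under 1.5-fold, among them Lims1 (-0.03) with JNK1-APF and Fggy (0.26) and Top2a (0.11) with MKK7ED.

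The other 6 lists lay within the middle 95% of random lists in each comparison. Medians ran from -0.10 to 0.11 for matrix proteases, where Mmp7 was at least 1.88-fold and 1.97-fold higher with H2O2 in uninfected and infected cells and at least 2.40-fold lower with JNK1-APF. They ran from -0.13 to 0.22 for JNK pathway components, from -0.20 to 0.03 for osteochondrogenic genes, from -0.10 to 0.20 for endothelial markers (8 measured), from -0.12 to 0.42 for macrophage and leukocyte markers (5 measured), and from -0.15 to 0.02 for fibroblast and adventitial markers (9 measured). Of the values of at least 2-fold, 90, 156, 120, 104, 75 and 168 were over 3 times the estimated error, in the order of the comparisons given at the start. Of the 132 medians of 22 lists in 6 comparisons, 35 lay outside the middle 95%, where independent genes would give 6.6. Members of a list can move together on a single array, and the comparisons share arrays. The excess over 6.6 therefore does not tell treatment effects from deviations of single arrays.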

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

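The tests of explanations in this part were all chosen after the results were seen. A gene or list was taken up here when its 2 H2O2 effects, in uninfected and in infected cells, went in opposite directions, a gene by at least 2-fold in each and a list in opposite outer 5% of the random lists, and the difference between the 2 effects was not tested for any of them, since each rests on 4 single arrays.

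Sterol and fatty acid synthesis genes had a median log2 fold of -0.44 with H2O2 in uninfected cells and 0.84 in cells with the nEGFP virus. A single deviating infected array is argued against, because the lowest median over the 4 pairs of infected arrays with and without H2O2 was 0.63, and scaling is argued against, because the median difference of the 2 effects was at least 1.26 under the 3 scalings. A deviating uninfected array cannot be told apart from a response that depends on infection, since the value of -0.44 comes from the single uninfected pair. Against the same untreated array, the nEGFP and MKK7ED arrays were at -0.49 and -0.54, and the nEGFP and JNK1-APF arrays with H2O2 at 0.24 and 0.17. An effect of H2O2 on sterol synthesis that depends on the virus may be the cause and stays an untested hypothesis.

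Of the 33 genes higher with MKK7ED plus JNK1-WT and lower with JNK1-APF, 25 had the JNK1-APF and nEGFP arrays below all 4 others, the uninfected arrays included. The genes were chosen for a low value on each of these arrays against its partner, so this count decides nothing, and a low signal shared by the 2 arrays stays open. A single lower scale factor for each of the 2 arrays as the whole cause is argued against, because 20 of the 33 genes were still called with equal array medians. Scale does matter in part, since the split of 33 and 5 genes became 20 and 14 there. Equal medians do not address a shift of weak signals only, and these 33 genes had a median signal of 49.3. JNK activity alone as what set their level predicts a low untreated array too, and in 13 of the 33 genes the untreated array was less than 1.5-fold above the nEGFP array, which leaves it open because the untreated array differs from nEGFP in the virus as well. Regulation by JNK within infected cells thus stays an untested hypothesis for these genes.

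On the JNK1-APF array 19 probe sets were listed at 0. Of these, 15 were above the floor with nEGFP and H2O2, so that a loss could be seen. For 5 of the 15, of Asnsd1, Pdha1, Irf7, Rab5a and Rasl11b, a loss of the transcript with JNK1-APF is argued against, because other probe sets of these genes had a median log2 fold of 0.063. The other 10 have no further probe set above 2 times the floor that is not itself at 0, and a loss stays open. A local fault of that array or its image is a candidate explanation, since 16 of the 19 lay within 400 consecutive places of the table.

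Smooth muscle contractile genes had medians of 0.09 and -0.80 with H2O2 in uninfected and infected cells, and over the 4 pairs of infected arrays with and without H2O2 the median ran from -0.80 to -0.19. The nEGFP array without H2O2 was itself at 0.28 against the untreated array. The single genes at least 2-fold apart in opposite directions, as log2 folds without and with virus, were Cntnap1 (1.07 and -1.28), Ptk2b (1.0 and -1.54), Snn (1.51 and -1.08), Acat2 (-1.13 and 1.03), Ddit3 (-1.41 and 1.19), Fabp5 (-1.45 and 2.10) and Muc5ac (-1.14 and 1.64). Among the 1123 probe sets above the floor without a single gene symbol, which the comparisons of genes leave out, 15 were at least 2-fold apart in opposite directions in the 2 JNK comparisons, 13 of them higher with MKK7ED plus JNK1-WT.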

How the results depend on the processing

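The settings without probe sets listed at 0 and without the stretch of zeros on the JNK1-APF array, and limma on 6 arrays, were chosen after the data were seen, and the other settings were planned. Values are numbers of genes at least 2-fold apart, in the order H2O2 uninfected (160 as reported), H2O2 infected (294), JNK1-APF (256), MKK7ED (255), virus without H2O2 (162) and virus with H2O2 (337), then the overlaps for H2O2 (20), JNK (38) and virus (24).

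With the floor at the 20th percentile (5.8) the counts were 498, 604, 631, 585, 511 and 714, with overlaps of 67, 119 and 100. With the floor at the 60th percentile (59.1) they were 38, 124, 85, 88, 54 and 138, with overlaps of 7, 10 and 10, and without a floor 791, 834, 911, 829, 761 and 935, with overlaps of 126, 197 and 159. By construction, a lower floor lets small signals form larger ratios. Signal over floor limits how far below its partner a gene can lie, so weak genes have bounds only. The mean of all probe sets gave 168 for JNK1-APF and 160 for MKK7ED, with overlaps of 10, 16 and 15, and the cause was not tested. At least 3-fold left 39, 60, 41, 41, 31 and 75, with overlaps of 1, 1 and 3, as a stricter threshold must leave fewer.

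Quantile normalization and equal array medians left each total within 1.5 times the reported one, but not each count by direction. With equal array medians the 77 genes higher and 179 lower with JNK1-APF became 133 and 114. The JNK overlap of 33 and 5 became 20 and 14, and 25 of the 38 genes were kept. Equal array medians moved the median log2 fold of genes with a mean signal over 100 by 0.20 for JNK1-APF, -0.11 for H2O2 in infected cells and -0.11 for MKK7ED. The median of ribosomal proteins with H2O2 in uninfected cells turned from 0.06 to -0.025 with equal array medians. That setting multiplies each array by a single factor, which moved genes with a mean signal over 100 by -0.0818 in this comparison. The change of sign follows from this rescaling. The 35 list results outside the middle 95% had 210 alternative values, for which percentiles were not recomputed. Of these, 163 differed from the reported median by less than 1 standard deviation of the random-list medians. Another 46 moved by more and 1 changed sign. Most of the moves came with the 60th percentile floor (17) and equal array medians (15).

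Limma on 4 arrays called 0 genes at an adjusted p of 0.05 for H2O2 and 0 for virus, with 167 and 296 at an unadjusted p of 0.05 against 182.85 by chance, and smallest adjusted p of 0.757 and 0.569. Limma on 6 arrays called 0 for JNK1-APF, 0 for MKK7ED and 0 in opposite directions, with 190 and 222 at an unadjusted p of 0.05 and smallest adjusted p of 0.712 and 0.658. It takes the single arrays with JNK vectors to vary like the others. Leaving out probe sets listed at 0 gave 248 for JNK1-APF, and leaving out the stretch gave 235 and a JNK overlap of 37. Limma on 4 arrays compares H2O2 within each virus state and virus within each H2O2 state. No other paired analysis was possible because each treatment has 1 array.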

Other observations

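The groupings of arrays in this part were chosen after the data were seen, and nothing in it was planned.

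Among the 4 infected arrays, 15 genes had both arrays with H2O2 at least 2-fold above both arrays without it, and 19 at least 2-fold below. The 19 include Rasl11b, whose probe set was listed at 0 on the JNK1-APF array. Higher with H2O2, given as mean folds, were for example Fabp5 (a fatty acid binding protein) 3.33, Scd 3.32, Lgals3 (galectin 3) 2.99 and Sds 3.07, and with an array at the floor Gja4 at least 5.17, Slc22a5 (the carnitine transporter) at least 3.21 and Des (desmin) at least 2.79. Lower with H2O2 were for example Npr3 (the natriuretic peptide clearance receptor) 4.47, Tgfb3 3.53, Actg2 3.14, Id1 2.94, Id2 2.75, Dusp1 (a MAP kinase phosphatase) 2.71 and Apoe 2.41. Over the 4 pairs of these arrays, medians ran from 0.63 to 0.87 for sterol synthesis genes and from -0.30 to -0.20 for growth factors. They varied more for contractile genes, from -0.80 to -0.19, for p53 genes, from 0.23 to 0.78, and for proliferation genes, from 0.02 to 0.71.

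Grouping the infected arrays in another way, 20 genes were at least 2-fold higher and 3 lower on the nEGFP with H2O2 and MKK7ED arrays than on the nEGFP and JNK1-APF arrays. With the JNK vectors against the nEGFP arrays there were 4 higher and 1 lower: Rsad2 at least 6.56-fold, Nrarp at least 3.66-fold, Syt5 3.38-fold and Pold1 at least 2.27-fold higher, and Kcnj4 at least 2.44-fold lower. The first of these, Rsad2, was higher with both JNK vectors even though they act on JNK in opposite ways, and so was Cxcl10, 4.10-fold with JNK1-APF and 4.99-fold with MKK7ED.

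Pairs of arrays at least 1.5-fold below all 4 others were most frequent for JNK1-APF with nEGFP plus H2O2 (34 genes, and 30 above) and for JNK1-APF with nEGFP (31, and 5 above), against 17 and 13 for the uninfected arrays. For comparison, nEGFP with MKK7ED had 5 above and 6 below.

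The JNK1-APF array had 9 probe sets listed at 0 whose median on the other arrays was over 100, and the other 5 arrays had 0. Steps of 32 to 37 places separate 10 pairs of its zeros. Among the 210 measured genes in the stretch from place 3267 to 3617, 5 were at least 2-fold higher and 16 lower with JNK1-APF, or 10.0% against 6.82% of the genes outside it. Of the 16 genes named for their size in that comparison, 10 lie in the stretch.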
